A study of Homo sapiens with 6 samples.

How the data were processed

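RNA sequencing was analysed for 6 libraries of hepatocyte-like cells that the labels describe as hepatoblasts at day 19. The cells were made from H9, a human embryonic stem cell line. There were 3 libraries from cells given 0.1% DMSO as vehicle and 3 from cells given HFPO-TA, hexafluoropropylene oxide trimer acid, a perfluoroalkyl ether carboxylic acid. A share of DMSO is recorded only for the DMSO libraries, so a matched vehicle in the HFPO-TA libraries is not established. The labels print the dose as 10 with a unit that cannot be read with certainty, so no unit is given here. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

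Each deposited file gave 1 value per gene for 60623 genes. The column header calls the values FPKM, but the columns of the 6 libraries sum to between 995690 and 996186, so the values were treated as TPM deposited by the authors. HISAT, Bowtie2 and RSEM and the build GRCh38.p13 are named per the submitters' processing notes, with no version and no role for each tool. The library kit, whether it kept strand, and the annotation used upstream are not given in the sources used here. TPM keeps no sequencing depth, so depth is unknown and no counting interval is given. The most frequent log2 ratio of low values to DMSO replicate 1 lay between -0.05 and 0.05 in the other 5 libraries.

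The test written before the data were examined was a count test, with limma on log2 values as the stated choice for files without counts. That second choice was used. Values were transformed to log2(TPM + 1), and genes with at least 1 TPM in 3 or more libraries were kept, which left 15664 genes. limma 3.58.1 in R 4.3.3 was fitted with treatment as the only term, with a trended and robust variance estimate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, 2-sided. Log2 fold changes are HFPO-TA minus DMSO on the log2(TPM + 1) scale, which understates the change of low genes. They are given with their standard error (SE), and levels are given as mean ± SD of 3 libraries.

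There were 26 gene lists, written before the data were examined, on hepatocyte functions, lipid and stress responses and cell types a stem-cell differentiation can hold. Of their genes 534 were found in the files and 453 passed the filter. The 25 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. camera's default variance setting was kept over a variance trend after results of both had been seen (5 lists called against 12). An estimated correlation, fry and ranks served as alternatives. Counts of members are given over all tested genes and adjusted over the list alone.

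Genes to name were set by a rule written before the data were examined. It took the 6 largest rises and 6 largest falls among called genes whose groups did not overlap, with a mean of at least 2 TPM and a symbol not based on a clone or locus number. It added the 2 called members with the smallest adjusted p of each list that was called or had 3 or more called members, and 1 member of each other list given as values. Where a called list had no called member, its member with the smallest p is given as values. It also took genes named in advance, among them PLIN2, ANGPTL4, PDK4, CPT1A, CYP7A1, CYP3A4, ALB, AFP, HNF4A, FASN, HSPA5 and HMOX1. Some genes that the rule took are not reported here. Other genes are named as chosen after their values were seen.

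Positions and gene types came from GENCODE 29 (GRCh38), in which 58516 of the 60623 gene identifiers were found; 107 tested genes had no entry there. Symbols are those of the files. Transcripts of genes listed at 0 throughout a group were compared with all other GENCODE 29 transcripts with blastn 2.17.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

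The fit was tested on simulated data for the comparison of HFPO-TA with DMSO, over 15664 genes with 200 changed, in 10 runs. It recovered 40.3% of genes changed by 0.5 on the log2 scale, 83.6% of those changed by 1 and 94.4% of those changed by 2. Unchanged genes made up 7.9% of the genes called in these runs, more than the adjusted p threshold of 0.05 implies. The simulation drew noise independently for each gene and library and placed changes only in genes above a low mean level. It held no structure shared between genes or replicates, so these rates may not hold for the real libraries. Alternatives covered the pseudocount, the filter, the variance estimate, a term for replicate number or for a possible batch, each library left out, gene type, scaling and the set test. Count-based alternatives were not run because the values are TPM.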

Results

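The 6 libraries held TPM values for 60623 genes, with 15383 to 15905 genes at 1 TPM or more in each. AFP, the fetal serum protein of liver cells, was the most abundant gene, at 7.69% ± 0.42 of all TPM with DMSO and 6.53% ± 0.19 with HFPO-TA (SD, n = 3 each). Mitochondrially encoded genes took 6.32% ± 0.11 and 6.63% ± 0.29 (SD, n = 3 each). The comparison addresses the transcriptional response to HFPO-TA, whose liver toxicity the series title names.

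PLIN2, which coats lipid droplets, rose with HFPO-TA from 108 ± 8.04 to 430 ± 23.7 TPM (log2 fold change 1.99, SE 0.07, adjusted p = 5.8e-05). PDK4, a kinase that restrains glucose oxidation, rose from 5.46 ± 0.66 to 31.8 ± 3.69 TPM (log2 fold change 2.34, SE 0.13, adjusted p = 0.000546). RBP2, a cellular retinol-binding protein typical of the small intestine, rose from 290 ± 11.6 to 1235 ± 248 TPM (log2 fold change 2.07, SE 0.14, adjusted p = 0.00371). The 3 fibrinogen chains FGG, FGA and FGB fell, with log2 fold changes of -1.24, -1.20 and -0.97.

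**Figure D1:**
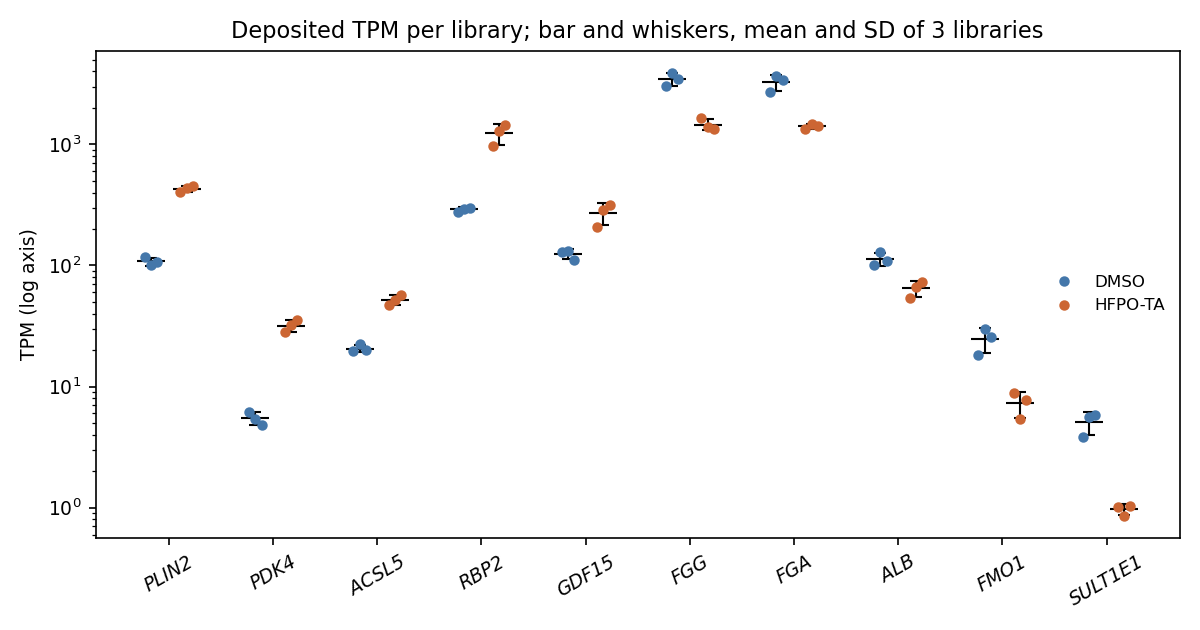
TPM on a log axis for 10 genes, with 1 point per library, blue for DMSO and orange for HFPO-TA; bar and whiskers are the mean and SD of 3 libraries. PLIN2 stands at 101 to 117 TPM with DMSO and 405 to 452 with HFPO-TA, while FGG stands at 3019 to 3882 and 1347 to 1636; ALB is plotted although it was not called (adjusted p = 0.0522).

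Across all 15664 tested genes, 77 changed, 29 of them higher and 48 lower with HFPO-TA. Of these, 21 changed by 2 times or more, 10 higher and 11 lower. At an unadjusted p under 0.05 there were 1882 genes, where 783 would be expected by chance. Members of a fixed list made up 18 of the changed genes, and 66 were protein-coding.

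ACSL5 and GDF15 were also among the 6 largest rises within the limits of the naming rule, a mean of at least 2 TPM over the 6 libraries and a symbol not based on a clone or locus number. ACSL5, which activates long-chain fatty acids, rose from 20.6 ± 1.48 to 51.8 ± 4.99 TPM (log2 fold change 1.29, SE 0.10, adjusted p = 0.00316). GDF15, a secreted stress-response factor, rose from 125 ± 11.4 to 270 ± 55.4 TPM (1.09, SE 0.15, adjusted p = 0.0418). In GENCODE 29 (GRCh38) PLIN2 lies on chromosome 9 from 19108375 to 19149290, PDK4 on chromosome 7 from 95583499 to 95596491 and RBP2 on chromosome 3 from 139452884 to 139480747. RBP2 lies wholly within AC046134.2 on the opposite strand, which stood at 8.02 and 8.39 TPM, and ACSL5 overlaps ZDHHC6, which stood at 14.7 and 14.3 TPM.

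Within the limits of the naming rule the largest falls were those of FMO1, SULT1E1, C20orf204, FGG, FGA and NANOGP1. FMO1, a flavin-containing monooxygenase, fell from 24.5 ± 5.78 to 7.32 ± 1.78 TPM (log2 fold change -1.61, SE 0.21, adjusted p = 0.0324). SULT1E1, the estrogen sulfotransferase, fell from 5.07 ± 1.10 to 0.97 ± 0.10 TPM (-1.61, SE 0.18, adjusted p = 0.0171; -2.249 with a pseudocount of 0.1). C20orf204 fell by 1.41 (SE 0.20, adjusted p = 0.0394) and NANOGP1 by 1.16 (SE 0.13, adjusted p = 0.0186) on the log2 scale. FMO1, SULT1E1 and NANOGP1 were each called in 2 of the 6 fits without a library, and C20orf204 in 1 (adjusted p up to 0.227). NANOGP1 is a pseudogene of NANOG and overlaps SLC2A14 on the opposite strand, so its reads may be shared and its value is uncertain.

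The list of PPARA targets and fatty acid oxidation genes was called higher as a set by camera at the preset correlation of 0.01 (adjusted p = 2.05e-12). With an estimated correlation (0.075) the call was lost (adjusted p = 0.252), and with fry it was kept (adjusted p = 0.00641). Of the 10 ways to split the 6 libraries into 3 and 3, 6 called as many lists as the real one, itself included. The camera p-values of the lists are therefore to be read with caution. PPARA is the nuclear receptor that governs fatty acid catabolism in liver. Of its 35 tested members 5 rose (among them PLIN2, PDK4, ACSL5 and CREB3L3), 1 fell (G0S2, an inhibitor of triglyceride breakdown) and 29 did not pass. Adjusted over the list alone, 15 rose and 1 fell. The median log2 fold change was 0.23, and 30 members lay above 0. CPT1A, the gate of fatty acid entry into mitochondria, stood at 5.70 ± 1.23 and 11.7 ± 1.38 TPM (0.93, SE 0.16, adjusted p = 0.0595). Its adjusted p was 0.045 with a term parting replicate 1 from 2 and 3 and 0.0962 with the replicate as a block, and 1 of the 6 fits without a library called it. ANGPTL4, a common PPARA target, stood at 17.7 ± 0.11 and 18.4 ± 2.18 TPM (adjusted p = 0.902).

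The list of secreted hepatocyte proteins was called lower as a set by camera at the preset correlation of 0.01 (adjusted p = 1.33e-09). The call was lost with an estimated correlation (0.479, adjusted p = 0.567) and with fry (adjusted p = 0.0553). Of its 26 tested members 5 fell (FGG, FGA, FGB, SERPIND1 and KNG1), none rose and 21 did not pass; adjusted over the list alone, 15 fell and 1 rose. The median log2 fold change was -0.38. FGG fell from 3458 ± 432 to 1458 ± 156 TPM (SE 0.11, adjusted p = 0.00857) and FGA from 3263 ± 487 to 1412 ± 67.0 TPM (SE 0.11, adjusted p = 0.00924). Albumin, ALB, stood at 113 ± 14.3 and 64.7 ± 9.84 TPM (-0.80, SE 0.13, adjusted p = 0.0522) and AFP at 76581 ± 4242 and 65021 ± 1828 TPM (-0.23, SE 0.05, adjusted p = 0.0867). Neither passed the test. Both did with a term parting replicate 1 from 2 and 3 (adjusted p = 0.0135 for ALB and 0.0109 for AFP) and neither with the replicate as a block (adjusted p = 0.0535 for each), and of the 6 fits without a library 1 called ALB and 0 called AFP. FGG and FGA lost their calls without DMSO replicate 3 or HFPO-TA replicate 2, and FGA also without HFPO-TA replicate 3 (adjusted p up to 0.0786). In the first 2 of these fits 0 genes were called lower, so FGB, SERPIND1, KNG1 and G0S2 lost their calls there too. With the replicate as a block FGG lost its call (adjusted p = 0.0718) and FGA kept it (adjusted p = 0.00689).

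**Figure D2:**
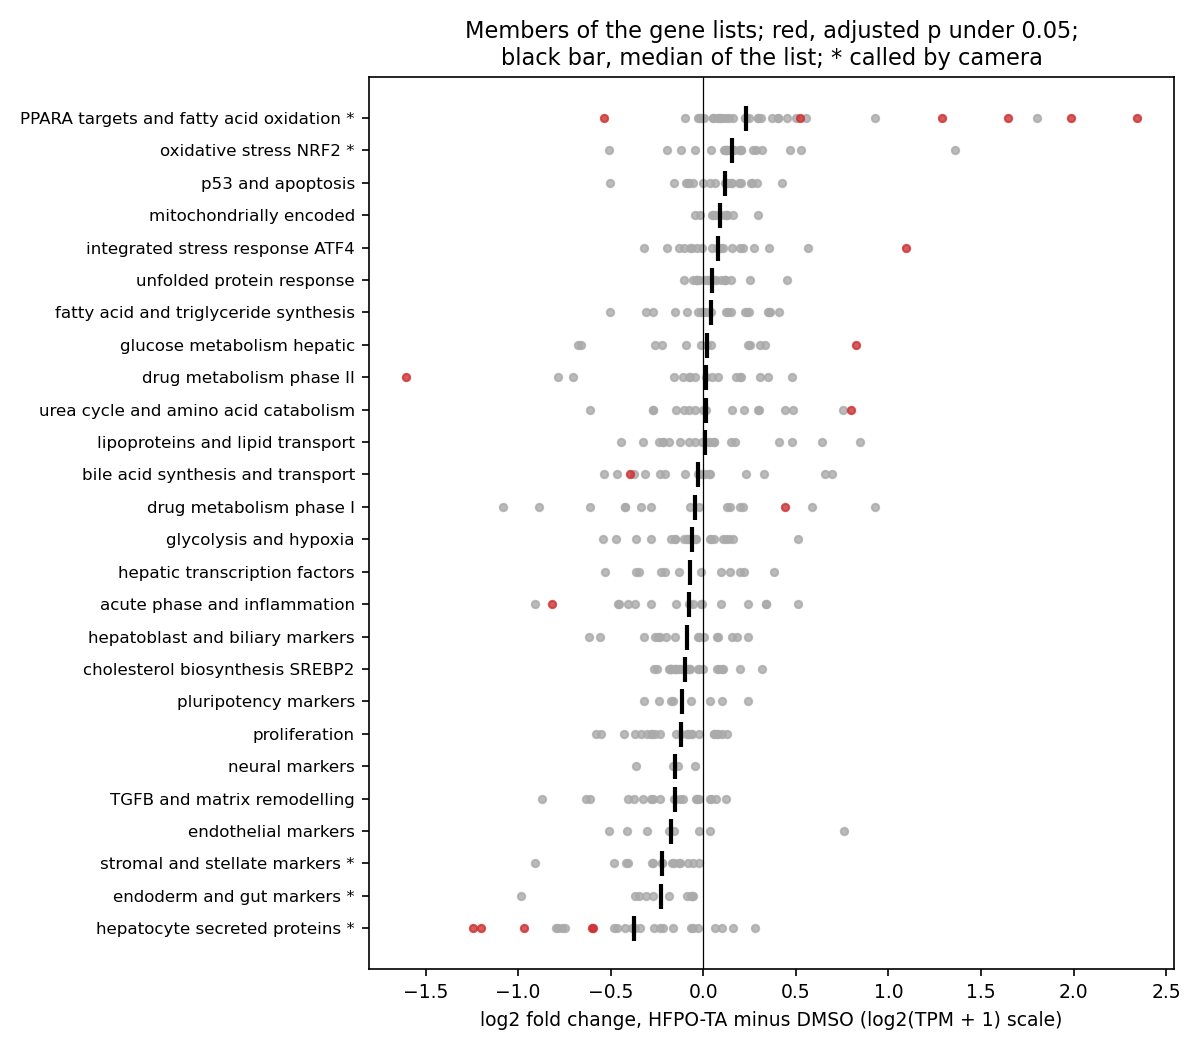
Log2 fold change (HFPO-TA minus DMSO, log2(TPM + 1) scale) of the tested members of the 26 lists, 1 point per gene, red where the adjusted p is under 0.05, with a black bar at the median. An asterisk marks the 5 lists called by camera; medians run from -0.38 for secreted hepatocyte proteins to 0.23 for PPARA targets.

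The other 3 lists called by camera had no called member. With fry, endoderm and gut markers kept the call (adjusted p = 0.00641). The NRF2 list and stromal and stellate markers lost it with fry (adjusted p = 0.0544 and 0.338). The NRF2 list of oxidative stress genes was higher (24 tested, 20 above 0, median 0.16, adjusted p = 0.00143; adjusted p = 0.489 with an estimated correlation), and adjusted over the list alone 0 members passed. Its smallest p belonged to OSGIN1 (43.6 ± 7.39 and 62.8 ± 4.04 TPM, adjusted p = 0.12), while HMOX1 stood at 33.5 ± 3.44 and 32.7 ± 6.11 TPM (adjusted p = 0.935). Endoderm and gut markers were lower (10 tested, 0 above 0, median -0.23, adjusted p = 0.00558; adjusted p = 0.32 with an estimated correlation), with 2 lower when adjusted over the list alone. TFF3, a trefoil peptide, stood at 4.03 ± 1.12 and 1.53 ± 0.47 TPM (adjusted p = 0.11). Stromal and stellate markers were lower (15 tested, 0 above 0, median -0.22, adjusted p = 0.0231; adjusted p = 0.567 with an estimated correlation), with 1 lower when adjusted over the list alone, and COL6A3 stood at 13.4 ± 0.87 and 9.32 ± 0.58 TPM (adjusted p = 0.11). That call ended without DMSO replicate 1, HFPO-TA replicate 2 or HFPO-TA replicate 3 (adjusted p up to 0.232).

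Single members of lists that were not called changed in both directions. CYP1A1, a drug-metabolising cytochrome P450, rose from 99.2 ± 4.37 to 135 ± 5.90 TPM (adjusted p = 0.0394). PCK1, a gluconeogenic enzyme, rose from 153 ± 28.6 to 269 ± 8.48 TPM (adjusted p = 0.0418), and CTH, which makes cysteine, rose from 9.33 ± 1.04 to 16.9 ± 0.50 TPM (adjusted p = 0.0324). FGFR4, the hepatic receptor of FGF19, fell from 152 ± 6.21 to 115 ± 3.71 TPM (adjusted p = 0.0419). LBP, a binder of bacterial lipopolysaccharide, fell from 7.93 ± 0.54 to 4.07 ± 0.46 TPM (adjusted p = 0.0451). Of the 6 fits without a library, 1 called each of CYP1A1, PCK1, FGFR4, LBP and GDF15, and 2 called CTH (adjusted p up to 0.249).

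The remaining lists were not called. Lipoprotein genes had a median of 0.01 (adjusted p = 0.699; 4 higher and 4 lower adjusted over the list alone), with APOC1 at 1142 ± 82.1 and 841 ± 85.5 TPM. Cholesterol synthesis genes had a median of -0.10 (adjusted p = 0.0869), with FDPS at 387 ± 17.4 and 324 ± 12.3 TPM. Fatty acid and triglyceride synthesis had a median of 0.04 (adjusted p = 0.0668), with SCD at 614 ± 42.1 and 783 ± 35.9 TPM and FASN at 371 ± 63.0 and 346 ± 9.82 TPM. Bile acid genes had a median of -0.03 (adjusted p = 0.311). Phase I drug metabolism had a median of -0.05 (adjusted p = 0.846) with camera pointing down and fry up. Phase II had a median of 0.02 and a mean of -0.10 (adjusted p = 0.929), with camera pointing up and fry down. The urea cycle and amino acid list had a median of 0.02 (adjusted p = 0.0869) and hepatic glucose metabolism 0.02 (adjusted p = 0.561). Adjusted over the list alone, higher and lower members numbered 1 and 1 for cholesterol synthesis, 4 and 0 for fatty acid synthesis, 2 and 3 for bile acids, 3 and 5 for phase I, 1 and 3 for phase II, 2 and 1 for the urea cycle list and 1 and 1 for glucose metabolism. Over all genes the only called members of these lists were FGFR4, CYP1A1, SULT1E1, CTH and PCK1.

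Stress and growth lists also stayed below the threshold. Adjusted p was 0.0563 for the integrated stress response (median 0.08), 0.157 for the unfolded protein response (0.05), 0.076 for p53 and apoptosis (0.12), 0.054 for proliferation (-0.12), 0.297 for glycolysis and hypoxia (-0.06), 0.294 for acute phase genes (-0.08), 0.054 for TGFB and matrix genes (-0.15) and 0.054 for mitochondrially encoded genes (0.09). HSPA5, a chaperone of the endoplasmic reticulum, stood at 391 ± 22.9 and 429 ± 83.2 TPM (adjusted p = 0.809), and HERPUD1 at 88.7 ± 7.75 and 121 ± 3.18 TPM (adjusted p = 0.0595). GADD45A stood at 75.5 ± 5.42 and 101 ± 2.18 TPM, NDRG1 at 204 ± 22.4 and 293 ± 44.3, MCM5 at 6.56 ± 0.13 and 4.10 ± 0.67, MMP14 at 154 ± 11.4 and 127 ± 12.6, and MT-ND2 at 2381 ± 97.1 and 2940 ± 385 TPM. Over all genes GDF15 of the integrated stress response and LBP of the acute phase list were called. Adjusted over the list alone, 2 members of the integrated stress response, 1 of the unfolded protein response and 1 of the p53 list were higher, 1 acute phase gene was lower, and 0 members of the other lists in this paragraph passed.

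Among lists of cell identity, hepatic transcription factors had a median of -0.07 (adjusted p = 0.309), with HNF4A at 49.3 ± 3.70 and 38.4 ± 1.21 TPM (adjusted p = 0.119). HNF4A-AS1 overlaps it on the opposite strand and stood at 26.01 and 16.98 TPM (adjusted p = 0.116), so without knowledge of strand the value of HNF4A is uncertain. Hepatoblast and biliary markers had a median of -0.09 (adjusted p = 0.054). Pluripotency markers had a median of -0.12 (adjusted p = 0.48; DNMT3B 7.43 ± 0.52 and 5.75 ± 0.25 TPM) and endothelial markers -0.17 (adjusted p = 0.28; EMCN 1.04 ± 0.24 and 2.47 ± 0.61 TPM). Neural markers, with 4 members above the filter, were not tested as a list (STMN2 29.6 ± 2.30 and 24.2 ± 11.2 TPM). No member of these identity lists was called over all genes; adjusted over the list alone, 1 transcription factor was higher and 3 lower, 4 hepatoblast and biliary markers were lower, 1 endothelial marker was higher and 0 pluripotency or neural markers passed. CYP7A1 and CYP3A4 lay below the filter, at 0.01 ± 0.02 and 0 TPM and at 0.46 ± 0.24 and 0.98 ± 0.61 TPM.

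**Figure D3:**
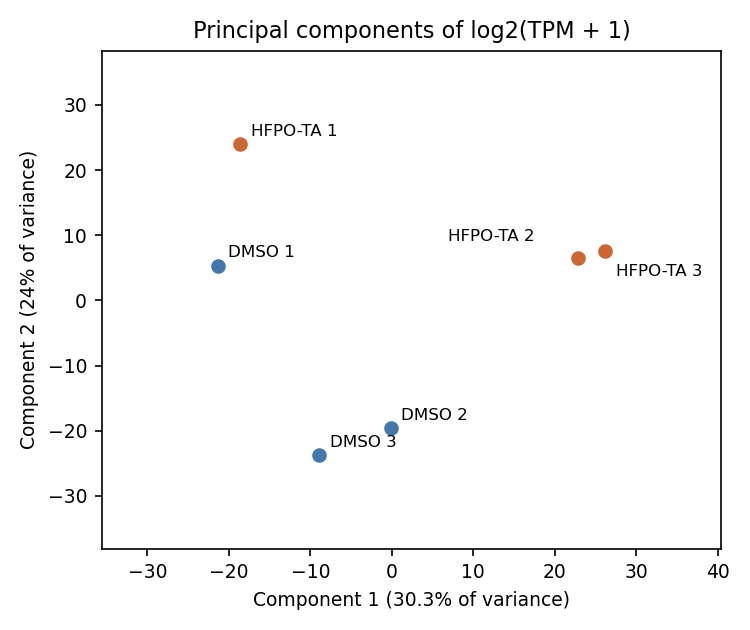
First 2 principal components of log2(TPM + 1) over the tested genes, 1 point per library, blue for DMSO and orange for HFPO-TA. Component 1 (30.3% of variance) places HFPO-TA replicates 2 and 3 at 22.8 and 26.2 and HFPO-TA replicate 1 at -18.6, near DMSO replicate 1 at -21.4.

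The counts depended strongly on which libraries were fitted. Leaving out 1 library gave from 6 changed genes (without HFPO-TA replicate 2) to 291 (without HFPO-TA replicate 1). They numbered 47, 14 and 7 without DMSO replicates 1, 2 and 3 and 10 without HFPO-TA replicate 3. Of the 77 changed genes, 75 kept the call without HFPO-TA replicate 1. Only 36, 11 and 7 kept it without DMSO replicates 1, 2 and 3, and 6 and 10 without HFPO-TA replicates 2 and 3. A fit with fewer libraries can call fewer genes for that reason alone. PLIN2, PDK4, RBP2 and ACSL5 were called in each of these 6 fits. A letter in the file names, unexplained by the labels, parts replicate 1 from 2 and 3 in both groups. Replicates 2 and 3 alone gave 222 changed genes, and 64 of the 77 kept the call. A term for the letter gave 207, and all 77 kept the call. Replicate 1 alone has 1 library per group and could not be tested.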

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

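Scaling, the removal of genes listed at 0, the removal of called members and the variance trend in camera were chosen after the data were seen. All 77 changed genes that were tested kept their direction in each of the 20 settings of the fit. Of the 17 called genes that the naming rule took, PLIN2, PDK4, RBP2 and ACSL5 were called in all 20, and the other 13 lost the call in 2 to 5 of the 6 fits without a library. Changed genes numbered 10 without a filter (60% higher, against 37.7%), 29 with a minimum of 0.1 TPM, 123 with a stricter filter, 30 with median-of-ratios scaling, 39 with upper-quartile scaling and 207 with a term parting replicate 1 from 2 and 3. The number with 2 times or more was 7 without a filter. With 1 library left out the counts ran from 6 to 291 changed genes, 5 to 62 by 2 times or more and 4 to 11 lists; without replicate 1 of both groups they were 222, 59 and 10. The share of higher genes then ran from 25.5% (without DMSO replicate 1) to 100% (without DMSO replicate 3 or HFPO-TA replicate 2). Fewer libraries were then fitted, and beyond that the cause was not tested. Called lists numbered 14 without a filter, 12 with the minimum of 0.1 TPM, 9 with the stricter filter, 8 with the term for replicate 1, 9 with protein-coding genes alone, 8 with median-of-ratios scaling and 12 with a variance trend in camera. With an estimated correlation 0 lists were called, against 5 with fry: PPARA targets, endoderm and gut markers and 3 that camera did not call, glycolysis and hypoxia, hepatic transcription factors and hepatoblast and biliary markers (lower, adjusted p = 0.0482 each). Ranks called 7 lists, the 5 and also TGFB and matrix genes (lower, adjusted p = 0.0356) and mitochondrially encoded genes (higher, adjusted p = 0.0224).

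The main fit did not pair replicates by number, and the labels state no block. Deviations correlated at 0.184, 0.123 and 0.028 for same numbers, -0.158 to 0.068 otherwise, so pairing stays open. Each library but HFPO-TA replicate 3 matched its number best. On log2 values, replicate 1 of each group correlated best with replicate 1 of the other group (r = 0.981). Replicates 2 and 3 of each group correlated best with each other (r = 0.9814 with DMSO and 0.9844 with HFPO-TA). With the replicate as a block 30 genes changed, 8 by 2 times or more, and 8 lists were called; 20 of the 77 genes were shared. Of the 17 called genes that the naming rule took, PLIN2, PDK4, RBP2, ACSL5, FGA, C20orf204 and NANOGP1 kept the call and the other 10 lost it, while APOC1 gained one (adjusted p = 0.0392).

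Signs turned only for named genes that were not called. FASN was at 0.043 without DMSO replicate 1 and 0.019 without replicate 1 of both groups, with a range of -0.193 to 0.043. HMOX1 reached 0.034 and its lowest value was -0.19. ANGPTL4 was at -0.03 without HFPO-TA replicate 3 and at most 0.132. Not run, since the values are TPM, were the count-based tests and size factors planned for count files. Depth is unknown, so what it limits cannot be stated.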

Other observations

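The tests of hepatocyte share, of TPM scaling and of gut-like cells were chosen after the results they measure were seen, as were the genes named here outside the rule. The tests of TPM scaling and gut-like cells replaced earlier ones whose values had been seen, a list median of -0.39 after scaling without the 10 highest and mitochondrial genes and, for gut-like cells, the enterocyte list given later and a median of -0.23 over all 10 endoderm and gut markers. The next 5 genes, of peroxisomes or of beta-oxidation and outside the fixed lists, were picked from the called genes after their values were seen. HSD17B4, a peroxisomal beta-oxidation enzyme, rose from 213 ± 8.67 to 307 ± 17.5 TPM (log2 fold change 0.52, adjusted p = 0.0248). SLC27A2, which activates very long-chain fatty acids, rose from 15.3 ± 1.03 to 27.7 ± 3.27 TPM (0.82, adjusted p = 0.0324). HSDL2 rose by 0.56, IDH1 by 0.50 and HADH, a mitochondrial enzyme of beta-oxidation, by 0.41 on the log2 scale (adjusted p = 0.0319, 0.0324 and 0.0476). Without HFPO-TA replicate 2 only 6 genes were called, PLIN2, PDK4, RBP2 and ACSL5 among them, so most of these 5 lost the call there. A list of 47 further peroxisomal genes left out genes already seen as called and those in the fixed lists. It had a camera p of 0.09 (direction up, p = 0.246 with an estimated correlation) and a median of 0.06 over 44 tested members. Of these 24 lay above 0 and 20 below, and 0 were called, also adjusted over the list alone. ACOX2, the member with the smallest adjusted p, stood at -0.49 (SE 0.10, adjusted p = 0.0901). Whether a wider rise may exist stays open, because a p above the threshold excludes nothing and the list left out called genes; the bound written beforehand, a p of 0.05 or more, was therefore wrong.

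Chance in the grouping of the libraries cannot be weighed closely, since 3 against 3 gives 10 splits and no share under 0.1. The real split gave 77 changed genes and 21 by 2 times or more, against at most 9 and 9 in the other splits; 1 of the 10 splits, the real one, gave as many. It called 5 lists, and 6 of the 10 splits called as many, with 11 in 2 other splits, both of which put DMSO replicate 1 and HFPO-TA replicate 1 on the same side.

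The fall of secreted hepatocyte proteins might reflect fewer hepatocyte-like cells or the TPM scale. Fewer such cells would raise markers of other cell types, but 45 tested markers of endoderm and gut, stromal, endothelial, neural and pluripotent cells had a median log2 fold change of -0.17 with quartiles at -0.31 and -0.06, and 5 lay above 0. A larger share of TPM for other genes would shift all genes alike, but the median of all tested genes was -0.00764, against -0.38 for the list. The median of all genes argues against the TPM scale as the whole cause. The marker value does not decide the share of hepatocyte-like cells. Several of these marker lists had already been seen to be lower, and hepatoblast and biliary markers were left out. Fewer hepatocyte-like cells and a change within them with HFPO-TA both stay open as hypotheses.

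RBP2 and LCT, genes of the intestinal lining, rose; LCT, lactase, went from 159 ± 10.97 to 305 ± 9.83 TPM (log2 fold change 0.94, adjusted p = 0.00239). More of the gut-like cells already present would raise their markers about alike, but the 5 intestinal markers of the endoderm and gut list (CDX2, CDH17, LGALS4, TFF3 and VIL1) had a median of -0.09, and the highest log2 fold change plus 2 SE among them was 0.18, against 0.81 for LCT minus 2 SE. A list of 24 enterocyte genes without RBP2, LCT and MEP1A, written before its test, went both ways and decides nothing: its 16 tested members had a median of -0.01 and quartiles at -0.31 and 0.19, 0 passed over all genes, and adjusted over the list alone 2 were higher and 1 lower, with FABP2 at 1.18 and MUC13 at 0.72 on the log2 scale. MEP1A, another gene of the intestinal lining, fell by 0.58 on the log2 scale (adjusted p = 0.0418). Like all lower genes, it lost its call without DMSO replicate 3 or HFPO-TA replicate 2. The 5 markers did not rise with LCT. They were picked after their values were seen, from a list already seen to be lower, so they do not decide against more of those cells. That explanation stays open. So does a small share of another gut cell type, which CDX2 at 61.6 ± 9.92 TPM with DMSO could hide. A change of these genes within cells with HFPO-TA stays open too.

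Among changed genes 3 were listed at 0 in all DMSO libraries and 1 in all HFPO-TA libraries. AC125388.1, an RPL39 pseudogene within ZNF525 on chromosome 19 (53386233 to 53386388), was listed at 0, 0 and 0 and at 23.9, 49.8 and 21.8 TPM. Its transcript matches RPL39 (2948 TPM on average) at 94.118% identity over 98.1% of its length, under the 95% set beforehand, and a ZNF525 transcript at 100%, so shared reads may account for it and cannot be told apart from a rise. The antisense genes OCIAD1-AS1, AC018761.2 and AC091564.2 overlap OCIAD1, PRDX2 and ILK, and no source used here says that strand was kept. The real split gave 5 tested genes at 0 on one side and at 1 TPM or more on the other. Below 10 TPM, a limit chosen after the values were seen, they numbered 4, and up to 6 in other splits. Another split gave 6 such genes with only 3 of them below 10 TPM, so zeros of higher genes also arose without the real grouping. These counts do not exclude chance zeros for any of the 5, AC125388.1 included. They are counts of genes per split and cannot weigh the zeros of a single gene, so chance zeros stay open.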
